A study of Homo sapiens with 14 samples.

How the data were processed

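Ribosome profiling sequences the mRNA fragments that translating ribosomes shield from nuclease, so the number of fragments assigned to a codon measures how often ribosomes were found there. Per the labels' protocols, footprints were made with RNase I in HEK293 cells, an immortalized human embryonic kidney line, that overexpressed a CFTR construct; the libraries were made by linker ligation, reverse transcription, circularization of the cDNA, rRNA depletion and PCR. CFTR is the chloride channel mutated in cystic fibrosis. The 14 libraries fall into 4 groups by the construct named in the labels: WT (n = 5), High-abc (n = 5), High-Leu558, in which the codon of Leu558 was changed from UUA to CUC (n = 2), and WT-Leu558-in-High-abc, in which High-abc carries the native Leu558 codon again (n = 2). All constructs encode the same protein with different synonymous codons. The labels do not list which other codons High-abc replaces.

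Per the file headers, each deposited file gives for a CFTR residue the read count and the percent of all CFTR-mapped reads. The deposited counts are whole numbers. The deposited percent equalled 100 times the count over the library's total within 0.0005, so only the counts were analysed and percentages were recomputed from them. Residues without a line in a file were taken as 0 reads. The submitters' processing notes name HISAT2 and hg38 without a version or role. The sequence to which reads were mapped, the read lengths kept and the rule that placed a read on a residue are not given in the sources used here, so a residue number here means the residue to which the authors assigned a read. No library had a read at residue 1. No molecular identifiers are mentioned, so intervals and limits from counts cover counting error only.

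The 20 residues at each end were left out, which left 1440 residues (21 to 1460). Changes per residue and per window of 10 residues were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM factors, filterByExpr, a quasi-likelihood fit of all 14 libraries with 1 term per group, glmQLFTest, and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 change is its size divided by the square root of the F statistic. The filter left 314 of 1440 residues, 21.8%, which held 64.5% of the reads, and all 144 windows. Beyond counting error, libraries of a group varied by a coefficient of variation of 53.4% per residue and 31.2% per window. These values come from edgeR's common dispersion over the residues or windows tested. Region shares, occupancies, polarity and profile correlations were tested by exact permutation of the library labels in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3); permutation tests were two-sided except that of the profile correlation, which was one-sided. Groups of 5 and 2 libraries cannot give a two-sided p below 0.0952 in that test. Occupancy is the number of reads at a residue, or the mean over a window, divided by the library's mean per residue. For the single residue, 0.5 reads were added before taking log2. The effect of the native Leu558 codon over both backgrounds was tested by relabelling libraries within each background, which gives 441 relabellings and a smallest p of 0.00454. Regions end at rounded residue numbers (80, 390, 500, 560, 650, 840 and 1200) and only approximate the domains after which they are named.

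Groups, the main tests, alternatives and the rule for naming residues were fixed before the data were examined. The permutation tests of percentages at Leu558 and its neighbours were not among the planned tests. Nor was that of the difference between backgrounds at Leu558. The rule named up to 10 residues and 10 windows in each direction per comparison, past an adjusted p of 0.05 with no overlap between libraries, the 8 regions, Leu558 with its neighbours and its window, and the 5 residues with the highest occupancy in WT and in High-abc. Alternatives were other scalings (library totals, TMM factors without NBD1, library medians, DESeq2 1.42.0 with its Wald test), other filters, other windows and boundaries, the ends kept, the most covered 1% of residues left out, only the 2 groups compared, the replicate number as a block, and each library left out in turn. The labels number the replicates without saying what a number shares. Deviations from the group mean of same-numbered WT and High-abc libraries correlated in all 5 pairs (r from 0.406 to 0.563, against a median of -0.162 for other pairs), so the numbers were taken to pair these libraries; the pairing comes from the data. In the groups of 2 there are too few pairs for this check. Nothing in the labels says whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No 2 libraries held identical values.

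Data were simulated 20 times, with 200 changed residues among 1440. The draws used each residue's mean share over all libraries, the real library sizes and 1 common spread. The edgeR test was then applied to them. In the design of High-abc against WT it recovered 67.1% of the tested residues with a 4-fold fall and 98.4% of those with a 16-fold fall, and 3.74% of its calls were false. In the design of High-Leu558 against WT it recovered 34.8% and 91.4%, and in that of WT-Leu558-in-High-abc against High-abc 49.2% of 4-fold and 99.1% of 16-fold rises. In 20 simulations without any change it called 0 residues and 1 window. The simulated libraries were drawn independently, without the correlation of same-numbered libraries and without a spread of its own for each residue. Of 99 other splits of the real WT and High-abc libraries, 11 called a residue. The simulated rates may therefore not carry over to these data. The planned comparison of codon usage with occupancy needs the coding sequence of CFTR and was not analysed here. Figures were drawn with matplotlib 3.10.9.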

Results

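Ribosome footprints along CFTR were compared between 4 constructs that encode the same channel protein with different synonymous codons, expressed in HEK293 cells. The endogenous CFTR gene lies on chromosome 7 at 117480025 to 117668665 (GRCh38.p14), but the constructs were expressed heterologously and positions below are residues of the protein, up to residue 1480. The number of CFTR reads ranged from 2463 (High-abc replicate 3) to 32630 (WT replicate 2), with a median of 6374, so an average residue held between 1.66 and 21.9 reads per library. Between 775 and 1337 residues had at least 1 read in a library. A residue with 0 reads allows a share of up to 0.122% in the shallowest library and 0.00919% in the deepest.

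The first comparison asked how the synonymous codons of High-abc alter the ribosome profile of CFTR. Footprints fell at Leu558, a residue of the first nucleotide-binding domain (NBD1), and at the residue after it. In WT, Leu558 held 0.860% ± 0.287 of CFTR reads (SD, n = 5; 467 reads in all), which made it the residue with rank 7 of 1440 by occupancy, at 12.8 times the mean residue. In High-abc it held 0.0297% ± 0.0154 (SD, n = 5; 9 reads), rank 816, a level 28.9 times lower. The residue after it, 559, held 0.188% ± 0.120 in WT and 0.0190% ± 0.0193 in High-abc (SD, n = 5 each). Every WT library lay above every High-abc library at both residues.

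By edgeR's quasi-likelihood test, 2 of the 314 residues tested changed between High-abc and WT. The log2 change was -4.88 (SE 0.65, adjusted p = 2.46e-07) at Leu558 and -2.88 (SE 0.66, adjusted p = 0.0103) at residue 559. An exact permutation test of the percentages, which was not planned, gave p = 0.00794 at each of these 2 residues, 0.0476 after Benjamini-Hochberg adjustment over 12 tests. With the replicate number as a block, 4 residues changed with all libraries in the fit: residues 569 and 595 also rose. With the block in WT and High-abc alone and the same 314 residues, 2 passed, Leu558 and residue 559. With only WT and High-abc in the fit and in the filter, 107 residues were tested, residue 559 not among them, and Leu558 alone passed. The residue before Leu558, 557, held 0.176% ± 0.145 in High-abc and 0.0356% ± 0.0212 in WT (SD, n = 5 each), a log2 change of 2.22 (SE 0.77) that did not pass (edgeR adjusted p = 0.312).

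**Figure D1:**
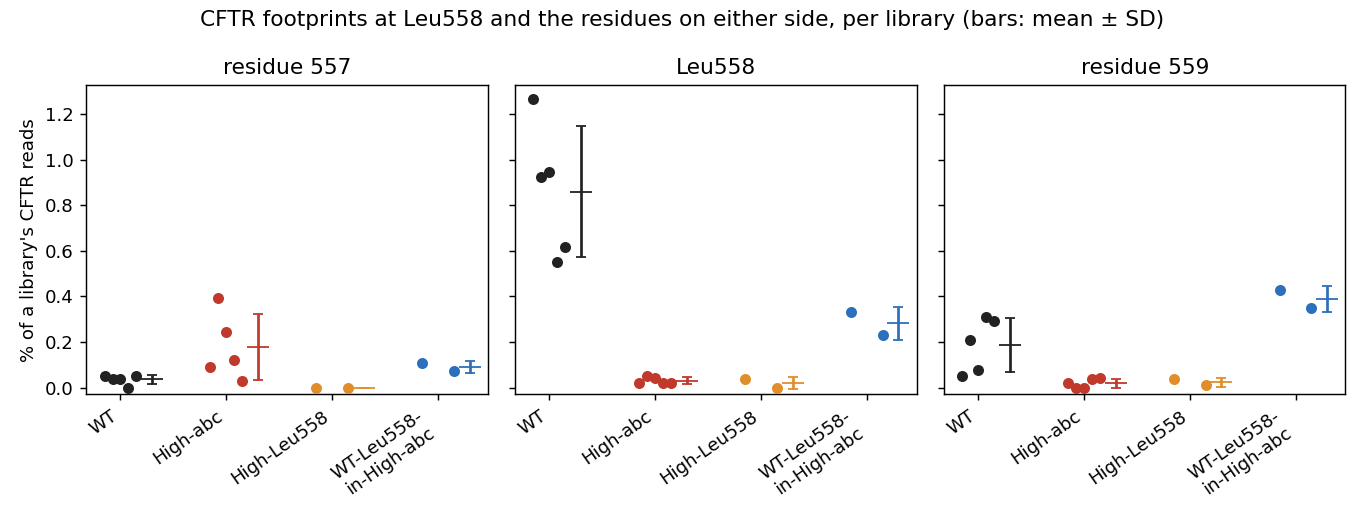
Percent of each library's CFTR reads (y axis) at residue 557, Leu558 and residue 559 in the 4 groups; points are libraries, bars the mean ± SD. At Leu558 the 5 WT libraries sit between 0.552% and 1.26% and the 5 High-abc libraries between 0.0180% and 0.0514%.

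In windows of 10 residues, the window from 551 to 560 fell from 1.45% ± 0.150 of reads in WT to 0.499% ± 0.237 in High-abc (SD, n = 5 each), a log2 change of -1.55 (SE 0.33, edgeR adjusted p = 0.0148). It was the only 1 of 144 windows to pass. With the replicate block 2 windows passed, the other being 591 to 600, which held 0.451% ± 0.106 in WT and 0.894% ± 0.349 in High-abc (SD, n = 5 each). With only the 2 groups in the fit, the 551 to 560 window did not pass without the block (log2 change -1.54, SE 0.35, edgeR adjusted p = 0.0585) and passed with it (-1.62, SE 0.25, edgeR adjusted p = 0.00463). No window of 20 residues passed in edgeR (2 had an unadjusted p under 0.05). The call was also lost without High-abc replicate 1, 4 or 5 (edgeR adjusted p = 0.103, 0.110 and 0.0697), with log2 changes of -1.41, -1.43 and -1.36.

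The second comparison asked what the single change of the Leu558 codon from UUA to CUC does in the WT sequence. In High-Leu558, reads at Leu558 fell to 0.0186% ± 0.0263 (SD, n = 2; 4 reads), 46.2 times below WT. Replicate 1 had 4 reads there and replicate 2 had 0 of 10157, which allows a share of up to 0.0295%. The log2 change at Leu558 was -5.43 (SE 0.96, edgeR adjusted p = 0.00022), and it was the only 1 of 314 residues to pass. The window from 551 to 560 fell to 0.261% ± 0.0913 (SD, n = 2), a log2 change of -2.53 (SE 0.47, edgeR adjusted p = 0.00369), and was the only window to pass. In it, Leu558 and residue 559 together held 0.0422% ± 0.0457 of reads (SD, n = 2), against 1.05% ± 0.183 in WT (SD, n = 5). Residue 559 held 0.0236% ± 0.0194 (SD, n = 2), with a log2 change of -2.95 (SE 0.89) that did not pass (edgeR adjusted p = 0.261). Residue 557 held 0 reads in High-Leu558 and 0.0356% ± 0.0212 in WT (SD, n = 5, 19 reads in all), with overlap between the libraries of the 2 groups. Without High-Leu558 replicate 2, edgeR called 0 residues (Leu558 adjusted p = 0.208), and the log2 change at Leu558 was -4.52, with a level in replicate 1 23.1 times below WT. Without replicate 1 the remaining library had 0 reads there, at least 29.1-fold lower than WT (against a floor of 3 reads per library); the fitted log2 change was -9.27 and is no bound. Without either replicate the window did not pass (log2 change -2.91, SE 0.71, edgeR adjusted p = 0.0723 without replicate 1, and -2.28, SE 0.67, edgeR adjusted p = 0.370 without replicate 2); the remaining library is then assumed to vary like those of the other groups.

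The third comparison asked what the native Leu558 codon does in the High-abc sequence. In WT-Leu558-in-High-abc, footprints rose at Leu558 to 0.282% ± 0.0713 (SD, n = 2; 74 reads), 9.49 times the level in High-abc. At residue 559 they rose to 0.389% ± 0.0583 (SD, n = 2; 99 reads), 20.4 times the level in High-abc. The log2 changes were 3.26 (SE 0.74, edgeR adjusted p = 0.00777) at Leu558 and 3.87 (SE 0.73, edgeR adjusted p = 0.00072) at residue 559, and no other residue passed. By occupancy, Leu558 had rank 49 of 1440 in this group and residue 559 rank 27. No window passed in edgeR or in DESeq2 (8 windows had an unadjusted p under 0.05 in edgeR); the window from 551 to 560 held 1.03% ± 0.121 (SD, n = 2), a log2 change of 1.08 (SE 0.40, adjusted p = 0.703). Without WT-Leu558-in-High-abc replicate 1, edgeR called neither residue (log2 change 2.91, SE 0.95, adjusted p = 0.527 at Leu558 and 3.67, SE 0.94, adjusted p = 0.0641 at residue 559).

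Against WT, the level at Leu558 in WT-Leu558-in-High-abc was 3.05 times lower, a difference that did not pass (log2 change -1.62, SE 0.70, edgeR adjusted p = 0.761). At residue 559 the log2 change was 0.99 (SE 0.64, edgeR adjusted p = 0.820). In this comparison 0 residues and 0 windows passed in edgeR and in DESeq2; 16 residues and 5 windows had an unadjusted p under 0.05 in edgeR. With the replicate number as a block Leu558 passed (log2 change -2.03, SE 0.42, edgeR adjusted p = 0.00102). The numbers are not shown to pair the groups of 2. In WT-Leu558-in-High-abc, residue 559 held 58.2% ± 2.55 (SD, n = 2) of the reads of the 2 residues together, and in WT it held 19.6% ± 14.3 (SD, n = 5). The 2 residues together held 0.671% ± 0.130 (SD, n = 2) of reads in WT-Leu558-in-High-abc and 1.05% ± 0.183 (SD, n = 5) in WT.

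**Figure D2:**
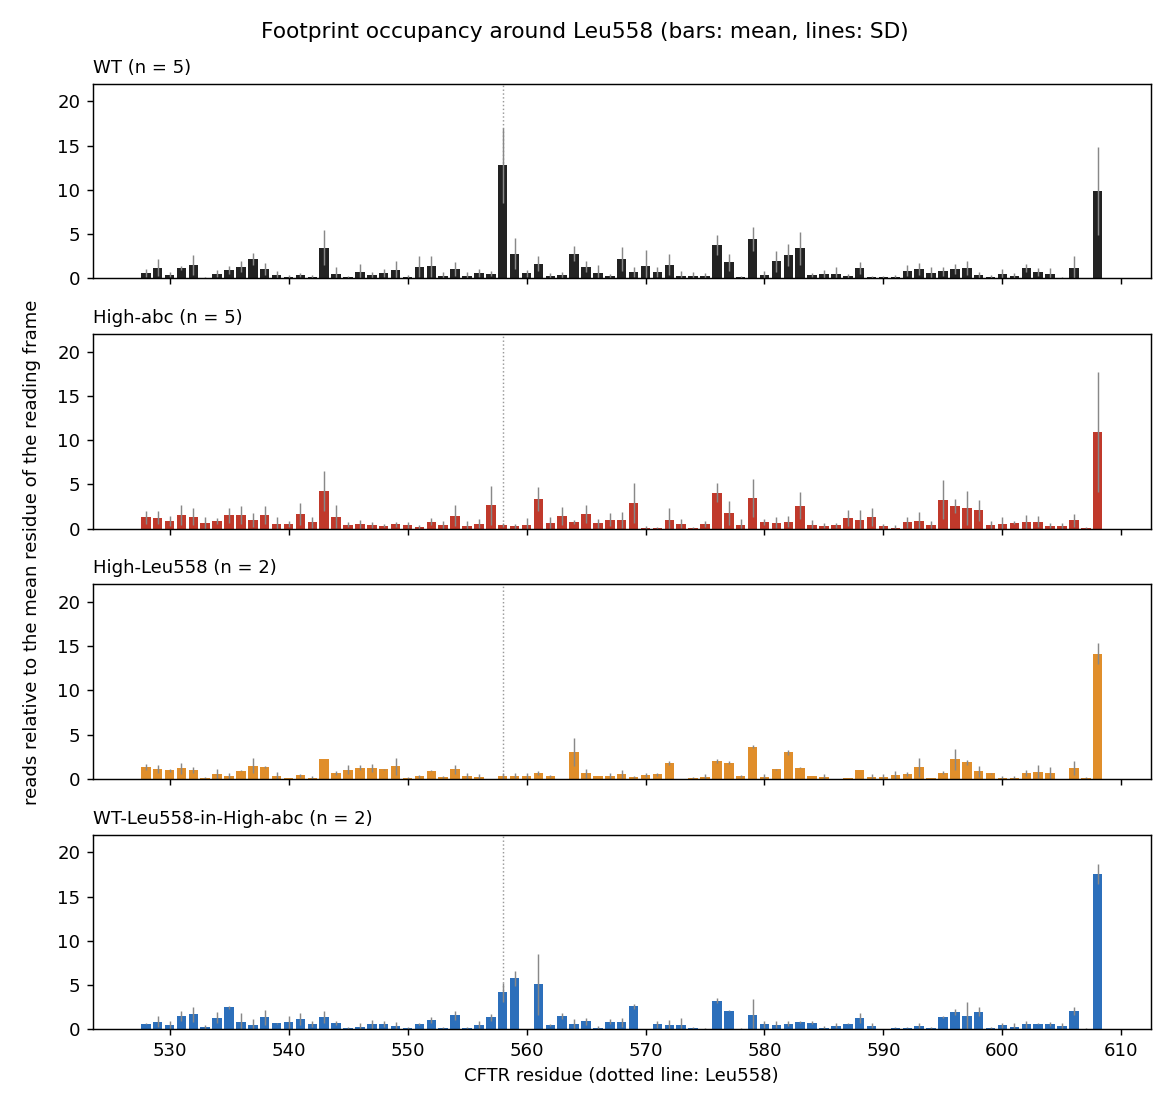
Occupancy, the number of reads relative to the mean residue of the reading frame (y axis), from 30 residues before to 50 after Leu558 (x axis) in the 4 groups; bars are means and lines the SD over libraries. Occupancy at Leu558 is 12.8 times the mean residue in WT, 0.442 in High-abc, 0.277 in High-Leu558 and 4.18 in WT-Leu558-in-High-abc. In WT-Leu558-in-High-abc residue 559 is higher than Leu558, at 5.76.

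Over both backgrounds, libraries with the native Leu558 codon had 21.4 times the occupancy at Leu558 of libraries with the replaced codon (log2 difference 4.42, exact permutation within backgrounds, p = 0.00454, the smallest p possible). Without High-Leu558 replicate 2 the occupancy was 12.5 times as high (log2 difference 3.65), and without High-Leu558 replicate 1, which leaves a library with 0 reads at Leu558, 36.5 times (5.19), a value that depends on the 0.5 reads added to each count. The log2 difference was 5.85 in the WT background and 2.99 in the High-abc background. The difference between the backgrounds was 2.86 (exact permutation p = 0.340). That permutation assumes no effect of the codon in either background, so it cannot decide whether the backgrounds differ. The interaction fitted in edgeR called 0 of 314 residues and 0 of 144 windows (18 residues and 6 windows at an unadjusted p under 0.05). DESeq2 called 0 and 0. With the replicate number as a block the interaction passed at Leu558 (log2 change -3.10, SE 0.99, edgeR adjusted p = 0.0280). The numbers are not shown to pair the groups of 2. In the window of 10 residues on either side of Leu558 (548 to 568), occupancy was 2.00 times higher with the native codon (log2 difference 1.00, exact permutation p = 0.0136). That mean includes Leu558 and residue 559, so it does not show a change at the other residues of the window. For single comparisons, that window changed by -0.84 on the log2 scale (SE 0.25) between High-abc and WT, with an exact permutation p of 0.0159 and 0.0635 after Benjamini-Hochberg adjustment over 4 comparisons. The ratio of density in the 30 residues before Leu558 to that in the 30 residues after it was 0.71 times as high with the native codon (log2 difference -0.49, exact permutation p = 0.0590), a quantity whose later part contains residue 559.

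**Figure D3:**
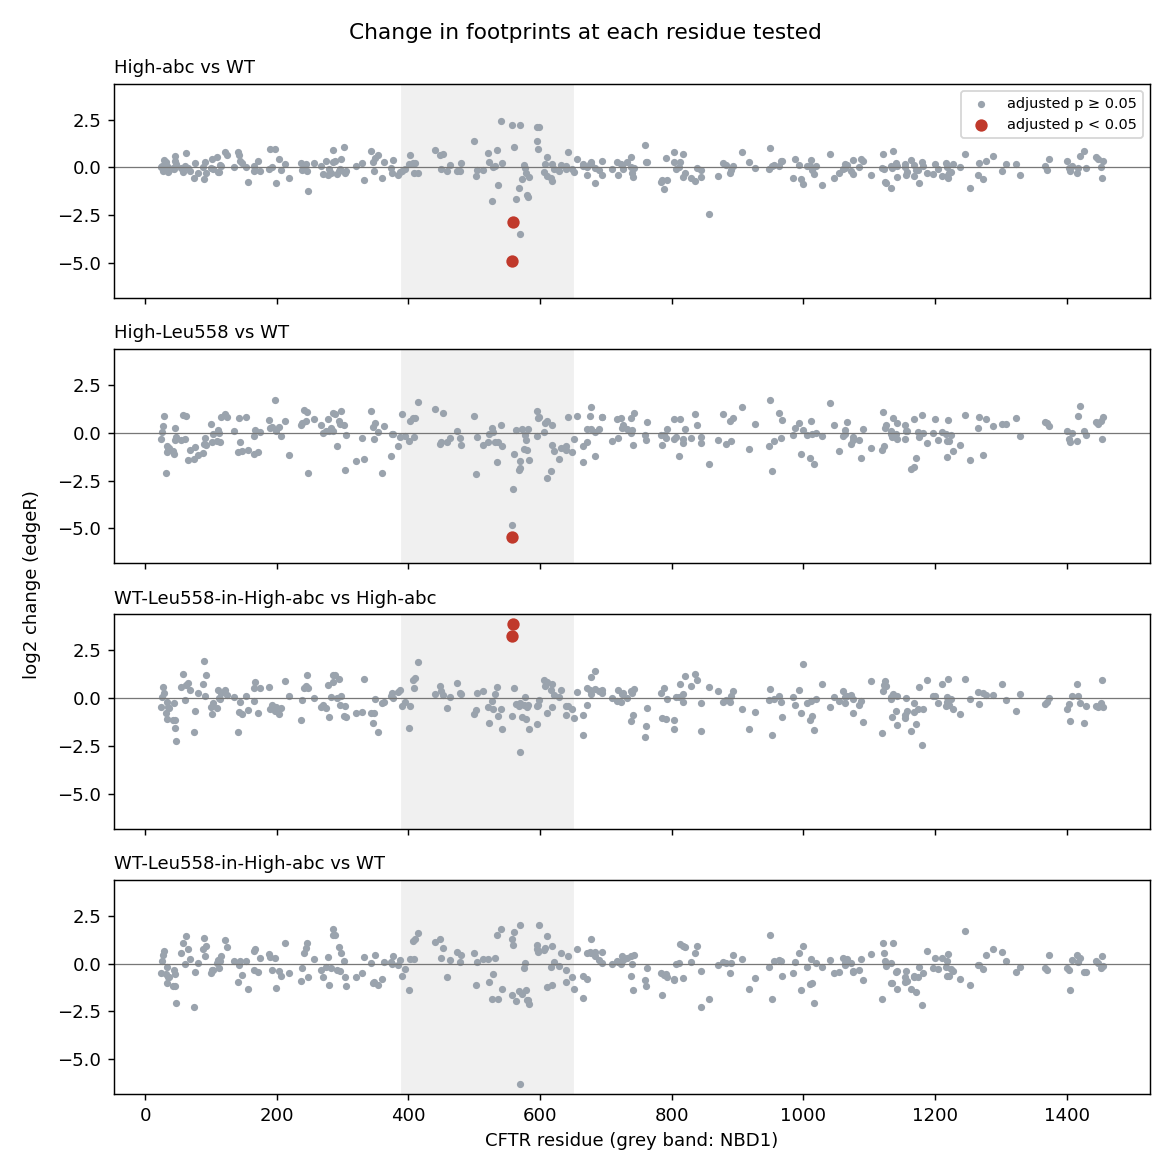
Log2 change from edgeR (y axis) at each of the 314 residues tested (x axis, residue number) in the 4 comparisons; red points have an adjusted p below 0.05 and the grey band marks NBD1. The red points are Leu558 and residue 559 in High-abc against WT and in WT-Leu558-in-High-abc against High-abc, and Leu558 alone in High-Leu558 against WT.

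The distribution of footprints over the 8 regions of the protein was compared next, to ask whether the constructs shift ribosomes between domains. The 3 NBD1 regions together (391 to 650) held 16.9% ± 1.39 of reads in WT and 17.2% ± 1.54 in High-abc (SD, n = 5 each), a log2 difference of 0.03 (SE 0.08, exact permutation p = 0.746); WT replicate 5, at 19.4%, lay apart from the other WT libraries. No region passed in High-abc against WT (exact permutation p from 0.270 to 1, each 1 after adjustment over 8 regions). The NBD1 alpha-subdomain region (501 to 560), which ends just after Leu558, held 4.71% ± 0.514 in WT and 4.40% ± 1.39 in High-abc (SD, n = 5 each). It held 3.29% ± 0.202 in High-Leu558 (SD, n = 2; exact permutation p = 0.0952 against WT, the smallest possible) and 4.05% ± 0.0186 in WT-Leu558-in-High-abc (SD, n = 2). The first and second membrane domains held 23.8% ± 1.17 and 25.0% ± 1.81 in WT, and 23.6% ± 2.41 and 25.1% ± 2.23 in High-abc (SD, n = 5 each). The NBD1 last part held 6.70% ± 0.796 in WT and 7.13% ± 0.265 in High-abc (SD, n = 5 each). Each remaining region differed between these 2 groups by less than the SD of either group.

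**Figure D4:**
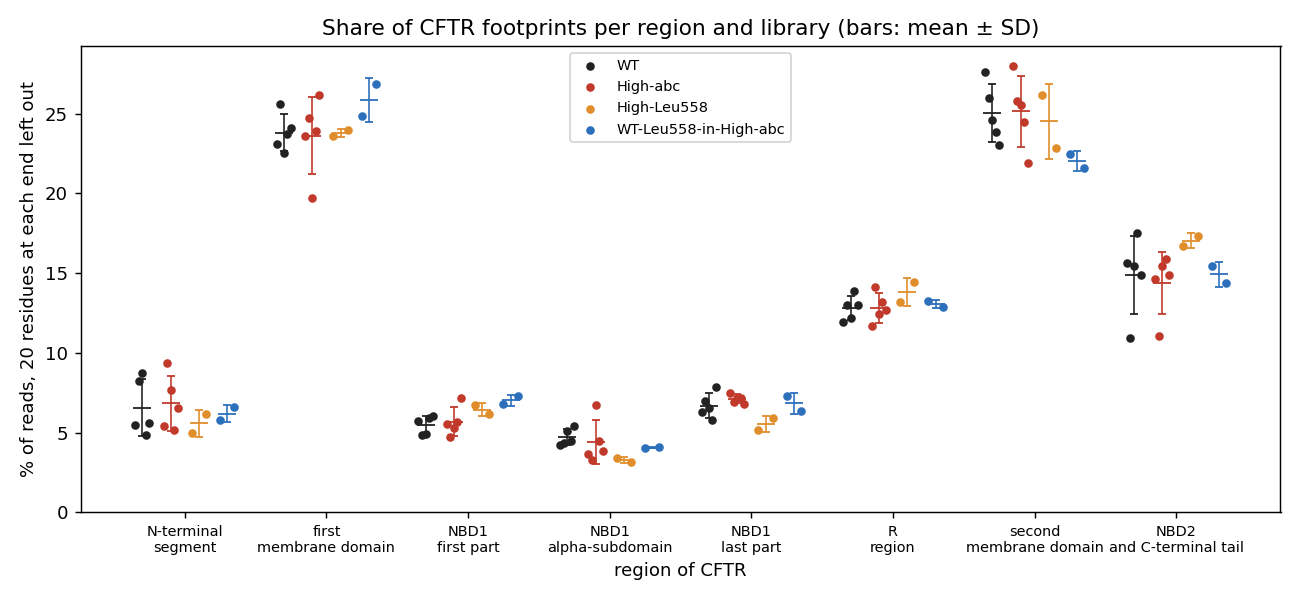
Percent of reads (y axis, 20 residues at each end left out) in the 8 regions of CFTR (x axis) for each library, coloured by group; bars are the mean ± SD. The shares of the first membrane domain, 23.8% in WT and 23.6% in High-abc, lie within the spread of either group.

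The balance between the 5' and 3' ends of the reading frame, a polarity from -1 to 1, was -0.0574 ± 0.0372 in WT and -0.0634 ± 0.0388 in High-abc (SD, n = 5 each; exact permutation p = 0.825). Over all 1440 residues, the mean Spearman correlation across residues, which are not independent replicates, was 0.520 within and 0.537 between WT and High-abc (one-sided exact permutation p = 0.833). The second mean includes the same-numbered pairs, which correlated at 0.629; it was 0.514 without them, 0.0064 below the first (one-sided exact permutation within numbers, p = 0.125, with 0.0625 the smallest possible), so these values show neither a difference nor its absence. The most covered residues were shared, with 4 of the top 5 common to WT and High-abc. Residue 1308, in the NBD2 and C-terminal region, had an occupancy of 36.6 ± 14.7 in WT and 40.9 ± 12.7 in High-abc. Residue 948, in the second membrane domain, had 28.3 ± 11.9 and 26.9 ± 8.87. Residues 1011 and 1075 of the same domain had 17.4 ± 9.90 and 15.8 ± 8.42 in WT, and 18.3 ± 11.8 and 20.2 ± 10.7 in High-abc (SD, n = 5 each). The remaining places in the top 5 were taken by residue 375 in WT (15.8 ± 6.73, against 12.8 ± 4.82 in High-abc) and residue 732 in High-abc (17.6 ± 6.86, against 15.1 ± 2.92 in WT; SD, n = 5 each).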

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

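In 48 sets of 5 libraries of WT or High-abc, 3 libraries stood far from the other 4 by Dixon's test, which flags about 1 set in 20 by chance. WT replicate 2 had 32630 CFTR reads, and the other WT libraries had between 2647 and 5839. High-abc replicate 2 had 11.0% of its reads in the NBD2 and C-terminal region, and the other High-abc libraries between 14.6% and 15.9%. WT replicate 5 had 19.4% of its reads in the 3 NBD1 regions, and the other WT libraries between 16.1% and 16.5%.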

How the results depend on the processing

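The fits of only WT and High-abc with the replicate block, the profile correlation over libraries with different numbers, the sign flips for polarity and the contrast of WT-Leu558-in-High-abc with High-Leu558 were chosen after seeing the data; the other alternatives were planned. The cause of the changes below was not tested, except where fewer libraries or residues were used.

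Counts of residues. Without a filter, 1 residue (822) was called in WT-Leu558-in-High-abc against WT and 1 in the interaction, where the main count was 0. With a mean of at least 20 reads, 1 residue was called in High-abc against WT and 1 in WT-Leu558-in-High-abc against High-abc, since residue 559 was not tested. With only the 2 groups compared, 1 residue was called in High-abc against WT, and 1 also with the replicate block added; residues 559, 569 and 595 were not tested there. Leaving out 1 library gave between 2 and 4 residues in High-abc against WT (4 without High-abc replicate 3), between 0 and 1 in High-Leu558 against WT (0 without High-Leu558 replicate 2), and between 0 and 2 in WT-Leu558-in-High-abc against High-abc (0 without WT-Leu558-in-High-abc replicate 1).

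Counts of windows. High-abc against WT gave 0 windows with only the 2 groups compared, 1 (551 to 560) with the replicate block added, and 0 in windows of 20 residues, and High-Leu558 against WT gave 0 in windows of 20 residues. Leaving out 1 library gave between 0 and 2 windows in High-abc against WT (0 without High-abc replicate 1, 4 or 5 and 2 without replicate 2), between 0 and 1 in High-Leu558 against WT (0 without either High-Leu558 replicate), and between 0 and 1 in WT-Leu558-in-High-abc against High-abc (1 without High-abc replicate 5).

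The replicate block. It raised the count in High-abc against WT from 2 to 4 residues and from 1 to 2 windows with all libraries in the fit; in WT and High-abc alone, with the same 314 residues, it gave 2 residues. The profile correlation within WT and High-abc, 0.0167 below that between them, was 0.0064 above it once same-numbered pairs were left out. In the groups of 2 libraries the numbers give 2 pairs per comparison, too few to check whether they pair samples. The deviations of 2 libraries mirror each other, and r ran from -0.0367 to 0.0454 in the 3 comparisons and was 0.128 between High-Leu558 and WT-Leu558-in-High-abc. By correlation of log2 read levels across tested residues, WT replicate 4 and High-abc replicate 4 were closest to High-Leu558 replicate 1 (r = 0.781 and 0.809). WT-Leu558-in-High-abc replicates 1 and 2 were closest to High-abc replicate 5 (r = 0.808 and 0.758). A block by number may therefore pair the groups of 2 with the wrong libraries. The block gave 19 residues and 18 windows in High-Leu558 against WT, 28 and 26 in WT-Leu558-in-High-abc against High-abc, 30 and 21 in WT-Leu558-in-High-abc against WT, and 42 and 39 in the interaction. Leu558 itself was among them: its log2 change in WT-Leu558-in-High-abc against WT was -2.03 (SE 0.42, edgeR adjusted p = 0.00102), and the interaction was -3.10 at Leu558 (SE 0.99, edgeR adjusted p = 0.0280) and -1.72 in the window from 551 to 560 (SE 0.57, edgeR adjusted p = 0.0335). Paired sign flips gave log2 differences of 0.8383 (window) and 4.5184 (residue) for the native against the replaced Leu558 codon, with p = 0.25 and 0.125 by exact permutation, where 0.125 is the smallest possible. The paired alpha-subdomain difference in WT-Leu558-in-High-abc against High-abc was 0.2244.

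Leu558 measures. The ratio before to after Leu558 passed with 15 residues on each side (-0.9813) and with 60 (-0.2855), and without 1 library it ran from -0.5909 to -0.4127 and passed only without High-abc replicate 2. Moved 5 residues towards the 3' end it was 0.5995, since the peak then lies in the earlier part. The single-residue occupancy moved 5 residues towards the 5' end was -0.3274, a residue away from Leu558. The window in High-abc against WT moved 5 residues towards the 5' end passed (-0.5903).

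Region shares, all without a call, changed sign as follows (log2 differences). With the top 1% of residues left out: first membrane domain 0.0055 and second -0.0035 in High-abc against WT, 0.0139 and 0.0411 in High-Leu558 against WT; in WT-Leu558-in-High-abc against WT, N-terminal segment 0.0146, NBD1 last part -0.0955 and NBD2 region -0.0098. With boundaries moved 10 residues towards the 3' end: R region 0.0047 in High-abc against WT, first membrane domain 0.0467 in High-Leu558 against WT, and N-terminal segment 0.0701 and 0.1057 in WT-Leu558-in-High-abc against High-abc and against WT. With boundaries moved towards the 5' end: in High-abc against WT, NBD1 first part -0.0553, alpha-subdomain 0.2481, last part -0.1283, R region 0.0255 and all NBD1 -0.0064; in WT-Leu558-in-High-abc against High-abc, NBD1 last part 0.0761 and R region -0.0101, and against WT, NBD1 last part -0.0522.

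Leaving out 1 library, differences in High-abc against WT ran from -0.0586 to 0.1751 (N-terminal segment), -0.0559 to 0.0466 (first membrane domain), -0.0447 to 0.1058 (NBD1 first part), -0.0359 to 0.0334 (R region), -0.0356 to 0.0533 (second membrane domain), -0.1514 to 0.048 (NBD2 region), -0.0139 to 0.0767 (all NBD1) and, for polarity, -0.0196 to 0.0072. In High-Leu558 against WT they ran from -0.0202 to 0.0259 and -0.1279 to 0.0679 in the first and second membrane domains. In WT-Leu558-in-High-abc against High-abc they ran from -0.2004 to 0.0124 (N-terminal segment), -0.1613 to 0.097 (alpha-subdomain), -0.1671 to 0.0368 (NBD1 last part), -0.0006 to 0.0687 (R region) and -0.0278 to 0.1177 (NBD2 region), and against WT from -0.1453 to 0.0659 (N-terminal segment), -0.069 to 0.1349 (NBD1 last part) and -0.0867 to 0.0833 (NBD2 region).

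Among the other recomputed values of the main comparisons, those without 1 library included, 463 kept their direction and their side of the threshold or stayed within 1.5 times the count. Pseudocount alternatives apply only to normalized values and were not run, nor was the comparison of codon usage, which needs the coding sequence. Depth limits the residues: 314 of 1440 held enough reads to test.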

Other observations

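The tests below were chosen after the results they bear on were seen, except the test of a footprint shift at other peaks, whose outcome was not known when it was set; its comparison with the WT libraries came after. Counting other splits of the libraries was planned, but the bounds for reading those counts were written after the counts were known.

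Along the last 2 NBD1 regions (501 to 650), several residues beyond Leu558 had an unadjusted edgeR p under 0.05 in High-abc against WT. Over all regions, 16 of the 314 residues tested had such a p, about the number that this threshold would give by chance alone. Of the 14 residues besides Leu558 and residue 559 with an unadjusted edgeR p under 0.05, 11 lay there, and the stretch, chosen for this reason, held 14.3% of the 314 residues tested. In the same count, 4 of 9 lay there in High-Leu558 against WT, whose sequences differ by the Leu558 codon alone, 8 of 15 in WT-Leu558-in-High-abc against WT and 2 of 10 in WT-Leu558-in-High-abc against High-abc. Residue 569 held 0.193% ± 0.149 of reads in High-abc and 0.0478% ± 0.0413 in WT, and residue 595 held 0.222% ± 0.146 and 0.0519% ± 0.0321 (SD, n = 5 each). Neither passed adjustment (edgeR adjusted p = 0.097 and 0.0745); both passed with the replicate block over all libraries (edgeR adjusted p = 0.0430 each), and neither with the block in WT and High-abc alone and the same residues (edgeR adjusted p = 0.215 and 0.198). The within-group correlation exceeded the between-group one by 0.105 in the alpha-subdomain region (one-sided exact permutation p = 0.0159, 0.127 after adjustment over 8 regions). Over libraries with different numbers the excess was 0.111, and 0.0464 without Leu558 and residue 559 (one-sided exact permutation within numbers, p = 0.0625, the smallest possible, and 0.125); the NBD1 last part (0.0563) and the R region outside the stretch (0.0189) also reached p = 0.0625.

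A hypothesis is that the construct sets this local profile, although the 4 of 9 residues above involve no High-abc background; the labels do not say which codons of the stretch differ between the High-abc and WT sequences. WT-Leu558-in-High-abc and High-Leu558 also differ by the High-abc and WT backgrounds and share no library with WT or High-abc, and between them 10 of the 11 residues (Leu558 and residue 559 left out) moved in the direction seen in High-abc against WT (exact sign test, p = 0.0117). Across the 43 tested residues of the stretch (again without Leu558 and residue 559) the changes in the 2 contrasts correlated (r = 0.734, Spearman rho = 0.568, permutation of residues, p = 1e-05, the smallest possible), against r = -0.103 in the 269 residues elsewhere. The sign test, this permutation and the bootstrap intervals below count residues, which are not independent replicates, so they measure no spread between libraries. The contrast of WT-Leu558-in-High-abc with High-Leu558 rests on 2 libraries per group. Uneven coverage as the whole cause is argued against by r = -0.0933 (95% bootstrap interval -0.235 to 0.0531) in the 166 residues elsewhere that were covered at least as well as the median residue of the stretch (interval 0.514 to 0.855 in the stretch). A change in mapping, cutting or ligation where bases differ could give the same pattern and stays open, since these files hold no read ends.

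The loss of reads at Leu558 where its codon was replaced was weighed against 2 technical explanations. If footprints over the changed codon had been lost in mapping, the 8 residues around it (554 to 563, Leu558 and residue 559 left out) should have fallen in High-Leu558 by at least 0.5 of the log2 change at Leu558; their log2 change was -0.777 (SE 0.269), against a bound of -2.71. Their share did fall, from 0.359% ± 0.152 in WT (SD, n = 5) to 0.196% ± 0.0126 in High-Leu558 (SD, n = 2). The bound assumes that reads placed on these residues cover the Leu558 codon. The rule that placed reads is not given, so this could not be checked. A loss in mapping, partial or whole, therefore stays open, and High-abc was not tested in this way. Differences between sets of libraries with a shared replicate number are argued against by a fall in all 5 pairs of WT and High-abc, the smallest of them -3.95 on the log2 scale. The fall in every pair follows from the lack of overlap between these groups given above, so it adds no separate evidence. The codon itself, which the design names, stays a hypothesis. Cutting or ligation that depends on the changed bases may also contribute and was not tested.

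In WT-Leu558-in-High-abc the reads leaned from Leu558 towards residue 559, with 56.4% and 60% of the reads of both residues at residue 559 in the 2 libraries, and between 3.95% and 36.0% in the 5 WT libraries. If footprints were placed 1 residue further downstream throughout, other peaks should show it: at the 30 most covered residues outside NBD1 the median share of the next residue was 11.2% ± 1.99 (SD, n = 2), 11.9% and 9.69% in the High-Leu558 libraries, 9.71% and 10.1% in High-abc replicates 4 and 5, from 3.40% to 6.43% in the other High-abc libraries, and 5.87% ± 1.26 in WT (SD, n = 5). The difference from WT, 5.35 percentage points (SE 1.51), lay below the bound of 9.66 set from the 38.6 at Leu558, but that bound assumed how far other peaks move when Leu558 does. In WT replicates 1 to 5 the shares were 4.79%, 4.79%, 5.71%, 7.85% and 6.19% at other peaks and 3.95%, 18.4%, 7.41%, 36.0% and 32.1% at residue 559, a slope of 8.87 (SE 4.09) that does not settle the scale. A shift that varies between libraries, and is not particular to this construct, could account for the pattern and stays open, as do the surrounding High-abc codons, which the design names and which were not tested.

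Other splits of the 10 WT and High-abc libraries into 5 and 5 were also tested. Of 100 splits drawn from 126, 10 called at least the 2 residues of the real split, with up to 23 in another split, so chance cannot be excluded from the count alone; 17 of 100 called at least the 1 window of the real split, with up to 16 in another. The split with 23 residues set WT replicates 1, 2 and 3 with High-abc replicates 1 and 2 against the rest, which points to a structure of the samples that follows the replicate numbers. None of the 99 other splits called Leu558. Each of them sets libraries with high and with low levels at Leu558 on both sides. The result follows largely from the lack of overlap given above and adds no separate evidence. Of the 16 splits that part every numbered pair, 1 (the real one) called as many residues, with 1 in the highest other, and 1 called as many windows, with 0 in the highest other; 16 splits are too few for a share under 0.05.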
